A study of Arabidopsis thaliana with 21 samples.

How the data were processed

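RNA from the aerial parts of 21-day-old Arabidopsis thaliana plants was hybridised by the authors to 21 single-channel Affymetrix arrays after biotin labelling, 3 arrays for each of 7 genotypes per the labels. RNA was isolated with a TRIzol kit per the labels. Whether the 3 arrays of a genotype came from separate plants, pools or harvests is not given in the sources used here. The deposited values are MAS5 signals of the unit intensity on a linear scale, MAS5 being named in the submitters' processing notes. The software version, detection calls and scaling target are not given in the sources used here. On every array the mean after leaving out the lowest and highest 2% of probe sets was 500, so the values had been scaled before deposition. No raw scans were used here.

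All 21 value columns were assigned to a genotype from the labels, and no 2 columns held identical values. The 64 AFFX control probe sets of 22810 were left out. Values were logged to base 2 with no second normalization, and the 30% of the other 22746 probe sets with the lowest mean log2 signal over all arrays (bound 5.257, a signal of 38.24) were left out, which kept 15923. The median signal per array was 131 to 187 and the 25th percentile 24.4 to 41.7.

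Probe sets were named from the annotation supplied with the series, which lists 14016 of them, 13436 with 1 gene and 503 with several. For 77 the listed gene had no match in the reference gene table, and 8730 were not listed. Of the tested probe sets 8761 (55.0%) had 1 gene. Probe sets with several genes or none were tested and counted but not named as genes. A locus code stands for a gene whose symbol is its locus.

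Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend) in 1 fit of 7 genotype means over all 21 arrays without a block. Probe sets with a Benjamini-Hochberg adjusted p under 0.05, two-sided and over the 15923 probe sets of a comparison, were called. The 12 comparisons were each of 6 genotypes against Col-0, each combination against aba2 and against its GA parent, and the interactions of aba2 with ga20ox1 and with GA20OX1-OE. All adjusted p-values of genes in the text come from limma. Tables and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

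Gene lists were tested with limma's camera at a preset correlation of 0.01, again with a correlation estimated for each list, and with fry, which asks whether a list's genes move on balance in 1 direction and does not compare them with other genes. Lists with at least 3 tested members entered, and p-values were adjusted over lists and comparisons, separately for 2 families. The first family was fixed before the data were examined, and 8 of its lists had enough tested members (96 tests). The second, of 26 lists (312 tests), was added after the annotation was read, because it named few members of the fixed lists, and before any fold change was computed, with members taken by name alone. For both, members were also adjusted over the list alone.

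The comparisons, the main test, the alternatives, the fixed lists and the rule for named genes were chosen before the data were examined. The rule takes ABA2 and GA20OX1 in every comparison. It takes the 5 largest rises and 5 largest falls per comparison among called probe sets with 1 gene whose arrays did not overlap between both groups, and for a list described the 2 largest rises and falls that were called. In interactions the overlap was not asked for. Neither ABA2 nor GA20OX1 was named by the annotation, so the rule found no value for them. Genes and probe sets named outside the rule are said to have been chosen after their values were seen.

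The alternatives were eBayes without the trend, array quality weights, the replicate number as a block, a fit of only the groups compared, no low-signal filter, a stricter filter leaving out the lowest 50% (11373 kept), a pseudocount of 20.1 (the 20th percentile of all values), quantile normalization, and leaving out each array in turn. Leaving out GA20OX1-OE replicate 2 and aba2/GA20OX1-OE replicate 3 together was added after seeing the data. Replicate numbers were not used as pairs in the main test, since no label says what a shared number stands for. Of 262 differences of named genes and key probe sets, 68 had at least 1 group under the low-signal bound, and 60 of these were also called with the pseudocount. In 2 of the 68 both groups lay under it, and 0 of these 2 were called with the pseudocount. No fold is given for any of the 68.

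The test was checked on simulated data with the spread of these arrays for aba2 against Col-0. Of 50 probe sets changed by a log2 of 0.5, 1, 2 or 3, it recovered 10%, 58%, 94% and 98%, with 8 false calls among the unchanged, and it made 0 calls in a comparison with no simulated change. The simulated noise was independent between arrays and probe sets, so this check does not cover structure shared by the real arrays. Shared Col-0 arrays were simulated 100 times with no true change.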

Results

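Gene expression was measured on single-channel Affymetrix arrays in the aerial parts of Arabidopsis thaliana plants grown in soil to an age of 21 days. The 21 arrays covered 7 genotypes with 3 arrays each. These were the wild type Col-0, the mutants aba2 and ga20ox1, the transgenic lines ABA2-OE and GA20OX1-OE, and the combinations aba2/ga20ox1 and aba2/GA20OX1-OE, all in the Col-0 background per the labels. ABA2 encodes an enzyme of abscisic acid (ABA) synthesis and GA20OX1 an enzyme of gibberellin (GA) synthesis, and OE commonly stands for overexpression. The title of the series places the question in how both hormones act on each other during leaf development. Each array held 22810 probe sets with a median signal of 131 to 187, and the correlation of log2 signals between arrays of a genotype was 0.966 to 0.982. Of 15923 probe sets tested, 8761 were assigned to 1 gene. Neither ABA2 nor GA20OX1 was among the genes named by the annotation used here, so their own transcripts were not followed by name. All values below are log2 signals or log2 differences with n = 3 arrays per genotype. The number of arrays limits their precision, and the p-values measure only the spread between these arrays, part of which may be technical.

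The genotypes with the aba2 mutation stood apart from the rest. In a principal component analysis of the tested probe sets, the 9 arrays carrying aba2 lay between 7 and 42.61 on the second component. The 12 arrays without it lay between -33.92 and 2.57, with the ABA2-OE arrays nearest to 0. The first component parted Col-0 replicates 1 and 2 (-27.6 and -24.02) from replicate 3 (10.15). It placed the ABA2-OE arrays, with median signals of 131 to 135, lowest and aba2/GA20OX1-OE replicate 3, with the highest median of 187, highest. That array also had the highest 25th percentile of signal, 41.7, and GA20OX1-OE replicate 2 stood apart from its group in QQS, at 6.68 against up to 11.19. Counts with both of these doubted arrays left out, a setting chosen after seeing the data, are given where they moved by more than 1.5 times.

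**Figure D1:**
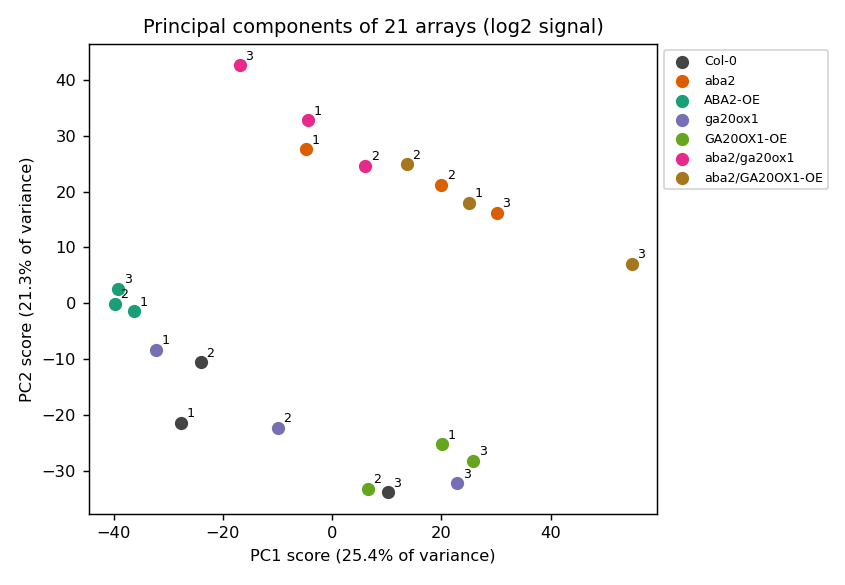
First and second principal components (25.4% and 21.3% of the variance, axes in component scores) of the log2 signals of 15923 probe sets. Each point is 1 array, coloured by genotype and numbered by replicate; the 9 arrays with aba2 lie above all arrays without it, from 7 upward on the second component.

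To ask what loss of ABA2 did to expression, aba2 was compared with Col-0. COR15A, a chloroplast protein gene induced by cold and ABA, had a mean of 9.18 ± 0.22 (SD) in aba2 and 12.83 ± 0.45 in Col-0, a fall of 12.6-fold (log2 difference -3.66, SE 0.33, adjusted p = 3.9e-07). HIS1-3, a drought-inducible linker histone gene, fell (-3.10, SE 0.49), and ZW9 fell 7.78-fold (-2.96, SE 0.16). The largest falls also included AT4G17470 (-4.80, SE 1.13) and the expansin-like gene EXLA1 (-2.85, SE 0.63). The largest rises were in AT1G66850 (6.18, SE 0.98), AT3G52130 (5.23, SE 0.75), ATA27 (4.74, SE 1.03), AT5G07230 (4.60, SE 0.94) and AT1G47980 (4.51, SE 0.76). AT1G66850, AT3G52130 and AT5G07230 belong to the lipid-transfer protein family, and ATA27 encodes an anther-associated beta-glucosidase. Their Col-0 means lay between 3.12 and 3.78, under the mean log2 signal of 5.257 that the low-signal filter required over all arrays. The size of such a difference depends on how the lower signal is treated, so no fold is given where at least 1 group lay under this bound. With a pseudocount these 5 rises stayed called at 4.19, 3.64, 3.2 (to 1 decimal), 3.21 and 3.18, and AT4G17470 and HIS1-3, under the bound in aba2, at -3.04 and -2.13. In ABA2-OE the means of the 5 rising genes were also above those of Col-0, at 5.19 to 7.07.

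All 4 tested members of the ABA-induced list fell in aba2, and all 4 also when adjusted over the list alone. Beside COR15A these were COR47 (-1.50, SE 0.19), COR15B (-1.19, SE 0.20) and the dehydrin gene LTI30 (-1.07, SE 0.20). The list median was -1.35 and its camera test gave adjusted p = 9.3e-11. With an estimated correlation the call missed the threshold (adjusted p = 0.05 with an estimated correlation). Of the 19 tested genes associated with drought, cold or ABA, 5 fell and 0 rose (median -0.32, camera adjusted p = 0.00071; adjusted p = 0.29 with an estimated correlation). The latter median was -0.14 without aba2 replicate 1, -0.21 without Col-0 replicate 1 or aba2 replicate 2, and -0.20 without aba2 replicate 3. Members of this list overlap with the shorter one.

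Cell wall and sugar transport genes moved in both directions in aba2. Among 6 tested expansins of the fixed list, which loosen cell walls, EXPA15 rose (1.31, SE 0.23) while EXPA16 (-1.56, SE 0.21) and EXPB1 (-1.42, SE 0.25) fell. Adjusted over the list alone, 3 rose and 2 fell. The median of this list was 0.36, whereas its mean of -0.05 and the direction of its camera test were negative (adjusted p = 0.89). Of all 12 expansins with a tested probe set 1 rose and 5 fell, among them EXLA2 (-2.73, SE 0.50). The xyloglucan-modifying gene EXGT-A3 fell (-1.34, SE 0.20), as did the endoglucanase gene GH9B8 (-0.81, SE 0.15). Of 12 tested SWEET genes, which encode sugar transporters, 5 rose and 2 fell. SWEET10 (3.48, SE 0.41) and SWEET3 (2.23, SE 0.35) led the rises. The falls were in SWEET13 (-1.16, SE 0.30, adjusted p = 0.026) and SWEET4 (-1.06, SE 0.17). As a list the 12 genes were not called (camera adjusted p = 0.22). With the pseudocount SWEET10, SWEET3 and EXLA2 stood at 2.78, 1.7 and -1.97.

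Further lists held few changes each. The plant defensin genes PDF1.2b (2.90, SE 0.45) and PDF1.2 (2.06, SE 0.37) were the 2 of 12 jasmonate and wound associated genes that rose. CYP71B22 rose by 1.84 (SE 0.24), UGT72E1 by 1.35 (SE 0.25) and the antenna protein gene LHCB4.3 by 1.10 (SE 0.21). LHCB4.3 was the only call among 18 nuclear photosynthesis and chlorophyll genes, whose median was -0.21, or -0.11 without Col-0 replicate 1. Of the UDP-glycosyltransferase genes UGT71C3 also rose (1.53) and UGT85A7 fell (-1.83). With the pseudocount UGT71C3 was not called (0.90, adjusted p = 0.052) and UGT85A7 stood at -1.26 (0.018). AOP1 of the glucosinolate list fell by 0.99 (SE 0.21), while the glucosinolate transporter gene GTR2 had a mean of 10.24 in aba2 and 9.62 in Col-0. Of 17 tested chloroplast-encoded ribosome and RNA polymerase genes 1 rose, rpoC1 (1.12, SE 0.30), and 7 rose when adjusted over the list alone (median 0.41, or 0.77 without Col-0 replicate 2, camera adjusted p = 0.0097; adjusted p = 0.59 with an estimated correlation). The other fixed lists with at least 3 tested members were not called by camera in aba2. Adjusted p was 0.60 for GA perception and DELLA genes (0 of 4 changed, also adjusted over the list alone) and 0.66 for the GASA family (1 of 4 rose, AT1G22690 by 0.89, SE 0.21, and 1 adjusted over the list alone). It was 0.82 for the XTH family (1 of 3, XTH19 by 1.72, SE 0.45), 0.54 for auxin response (1 of 3, GH3.3 by 1.52, SE 0.35), 0.82 for flavonoid and anthocyanin genes (0 of 4) and 0.42 for leaf senescence (0 of 3), with the same counts adjusted over the list alone. For auxin response the median was -0.02 and the mean 0.47. XTH19 was no longer called after quantile normalization.

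Markers of flowers were examined beside the genes that rose most. Of 9 tested flower, pollen and meristem genes, ATA27 rose and the actin gene ACT11 fell (-0.86, SE 0.19). The other 7 were not called, FD having a difference of 1.30 (SE 0.49) and INO of -1.51 (SE 0.48).

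In total, limma called 401 probe sets higher and 400 lower in aba2, 402 of them by 2-fold or more. This count of 801 was 524 without Col-0 replicate 1, 504 without aba2 replicate 2 and 491 without aba2 replicate 3, and without each of these more were lower than higher (273 and 251, 271 and 233, 266 and 225). The call of ATA27 ended without Col-0 replicate 1 (adjusted p = 0.054) or aba2 replicate 2 (0.058), and over all alternatives its adjusted p ran from 0.00089 to 0.058. The call of EXLA1 ended without Col-0 replicate 3 (0.059; range 0.00017 to 0.059), as did those of AT1G22690 (0.06; range 0.0032 to 0.06) and GH3.3 (0.064; range 0.00077 to 0.064). The call of AT4G17470 ended without Col-0 replicate 1, aba2 replicate 2 or aba2 replicate 3 (0.056 to 0.063; range 0.00016 to 0.063), and that of rpoC1 without the same 3 arrays (0.11 to 0.21; range 0.0056 to 0.21). XTH19 lost its call without any 1 of the aba2 arrays or Col-0 replicate 2 (0.05 to 0.14; range 0.013 to 0.14).

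**Figure D2:**
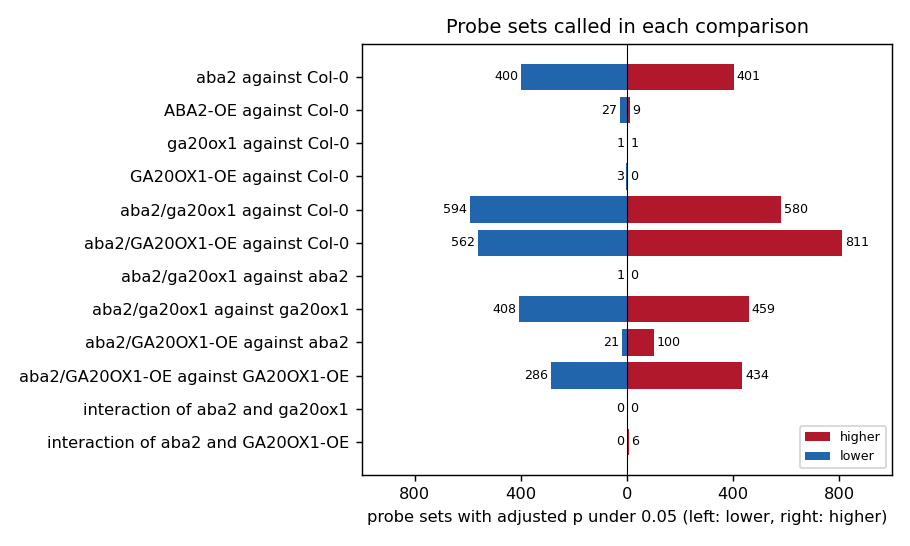
Number of probe sets called by limma (adjusted p under 0.05, x axis) in each of 12 comparisons (y axis), with bars to the right for higher and to the left for lower signal. The comparisons that add aba2 hold 720 to 1373 calls, and those of ga20ox1 or GA20OX1-OE with Col-0 hold 2 and 3.

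For the opposite change, ABA2-OE was compared with Col-0. AT3G52130 rose (3.60, SE 0.75, adjusted p = 0.046), and AT4G29980 (2.14, SE 0.42), AT3G15630 (0.72, SE 0.15) and AT1G27290 (0.64, SE 0.13) rose as well. AT1G47400, which encodes a peptide of the iron deficiency response, fell by 1.78 (SE 0.28, adjusted p = 0.01). Its mean was 7.68 in Col-0 and lower, 5.89 to 6.92, in every other genotype. The phosphoglycerate mutase gene PGM (-1.48, SE 0.29), the chaperonin gene Cpn60beta2 (-1.03, SE 0.19), AT3G51720 (-1.11, SE 0.19) and AT3G23940 (-0.75, SE 0.16) fell too. With the pseudocount AT3G52130 (2.15, adjusted p = 0.05) and PGM (-0.92, 0.054) were no longer called, and AT4G29980 stood at 1.37. The rise with the smallest limma p-value of any probe set was at 259669_at, which the annotation does not name and which was chosen after its values were seen. It stood at 13.61 ± 0.84 in ABA2-OE and 9.06 ± 0.25 in Col-0 (4.54, SE 0.26, adjusted p = 5.5e-10), and it was lower in aba2 than in Col-0 (-1.01, SE 0.26, adjusted p = 0.024).

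No member of the ABA-induced list passed in ABA2-OE over all probe sets, but 3 of 4 rose when adjusted over the list alone, LTI30 (0.90, SE 0.20), COR15A (0.87, SE 0.33) and COR47 (0.48, SE 0.19). COR47 was not called over the list without ABA2-OE replicate 1 (0.41), Col-0 replicate 2 (0.33) or ABA2-OE replicate 2 (0.31). COR15A was not without the same 3 arrays or Col-0 replicate 3 (0.64 to 0.90). The list median was 0.67 (camera adjusted p = 0.0032; adjusted p = 0.34 with an estimated correlation). The 40 chloroplast-encoded photosynthesis genes had a median of 0.30 (camera adjusted p = 6.3e-05; adjusted p = 0.58 with an estimated correlation), with 0 called over all probe sets and petA (1.0, SE 0.28) and ndhJ (0.74, SE 0.20) called over the list alone. Without Col-0 replicate 3 that median was 0.10 and petA stood at 0.58, and neither gene was called over the list without that array, Col-0 replicate 1 or ABA2-OE replicates 1 or 3. Limma called 9 probe sets higher and 27 lower, and 2738 had an unadjusted p under 0.05. This count of 36 was 242 without Col-0 replicate 2, 18 without Col-0 replicate 1 (9 higher and 9 lower), 3 without Col-0 replicate 3, 4 without ABA2-OE replicate 1, 12 without ABA2-OE replicate 2 and 17 without ABA2-OE replicate 3. It was 15 with array quality weights, 9 without the trend and 11, with 6 higher and 5 lower, when only the groups compared entered the fit. Of the genes named for this comparison, AT1G47400 alone kept its call without each array in turn. AT3G51720 lost it without ABA2-OE replicate 1 or Col-0 replicate 3 (adjusted p up to 0.13), PGM without either of these or Col-0 replicate 1 (up to 0.21), and Cpn60beta2 without Col-0 replicate 1, ABA2-OE replicate 2 or Col-0 replicate 3 (up to 0.13). AT4G29980 kept it only without Col-0 replicate 2 or ABA2-OE replicate 3 (otherwise up to 0.18), and AT3G52130, AT3G15630, AT1G27290 and AT3G23940 only without Col-0 replicate 2 (otherwise up to 0.14, 0.13, 0.27 and 0.29). Over all alternatives the adjusted p of the 8 genes that lost calls ran from 0.011 to 0.29.

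The ga20ox1 mutant was compared with Col-0 to see what loss of GA20OX1 did alone. Limma called 2 probe sets, named here after their values were seen. The probe set 251109_at, which the annotation does not name, rose (1.28, SE 0.17, adjusted p = 0.0038), and AT1G47400 fell (-1.71, SE 0.28, adjusted p = 0.037). In Col-0 the mean of 251109_at was 11.49, lower than in every other genotype (11.73 to 12.78). It was also called in ABA2-OE (1.19, adjusted p = 0.0043). The Col-0 mean of AT1G47400, 7.68, was higher than in every other genotype (5.89 to 6.92). For both, a deviation of the Col-0 arrays cannot be told apart from an effect of ga20ox1. An unadjusted p under 0.05 was found for 971 probe sets. Of 4 flavonoid and anthocyanin genes 3 were higher when adjusted over the list alone, UF3GT (1.47, SE 0.32), DFR (1.17, SE 0.44) and AT4G14090 (0.92, SE 0.39), with a list median of 1.05 (camera adjusted p = 0.0032; adjusted p = 0.34 with an estimated correlation). Of 4 GA perception and DELLA genes 2 were, the GA receptor gene GID1A (0.66, SE 0.14) and SLY1 (0.65, SE 0.26), with a median of 0.65, or 0.37 without Col-0 replicate 3 (camera adjusted p = 0.0032; adjusted p = 0.14 with an estimated correlation). Over the list DFR was not called without ga20ox1 replicates 1 or 3 or Col-0 replicate 2 (0.70 without the last), AT4G14090 without these or Col-0 replicate 3, and SLY1 without ga20ox1 replicates 1 or 2 or Col-0 replicates 2 or 3. GID1A and UF3GT had their lowest means in Col-0 (8.87 and 5.53) and their highest in ga20ox1 (9.53 and 7.01). The other genotypes lay at 9.14 to 9.43 and 5.63 to 6.39. Low values on the Col-0 arrays may thus be part of both differences.

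Chloroplast-encoded genes had positive medians in ga20ox1. Of 40 photosynthesis genes 15 were higher when adjusted over the list alone, such as atpI (2.1, SE 0.60) and psbN (1.28, SE 0.39), and 0 over all probe sets (median 0.43, camera adjusted p = 2.3e-12; adjusted p = 0.33 with an estimated correlation). Of 17 ribosome and RNA polymerase genes 8 were higher over the list alone, such as rpl20 (1.41, SE 0.28) and rpoC1 (1.29, SE 0.30), with a median of 0.67 (camera adjusted p = 2e-12; adjusted p = 0.29 with an estimated correlation). Both root markers were higher over the list alone beside these groups, PYK10 by 0.90 (SE 0.25) and EXPA18 by 1.62 (SE 0.60), though not over all probe sets. EXPA18 was not called over the list without Col-0 replicate 2 (0.91) or ga20ox1 replicate 1, atpI without Col-0 replicates 1 or 3 or ga20ox1 replicate 3, and psbN without Col-0 replicates 1 or 3 or ga20ox1 replicate 1. The ribosome and RNA polymerase list also had positive medians in aba2 (0.41) and GA20OX1-OE against Col-0. The photosynthesis list had one in ABA2-OE (0.30), but a negative one in aba2/GA20OX1-OE (-0.13). Both rpl20 (6.08, against 6.19 to 7.49) and rpoC1 (7.66, against 7.95 to 8.94) had their lowest mean in Col-0. A deviation of the Col-0 arrays thus cannot be told apart from an effect of ga20ox1 on these lists. The arrays of Col-0 and ga20ox1 also parted along another line. Setting Col-0 replicates 1 and 2 and ga20ox1 replicate 1 against Col-0 replicate 3 and ga20ox1 replicates 2 and 3 gave 370 calls, with the expansins EXPB1 (-1.19), EXPA8 (-0.90) and EXPA15 (-0.72) lower in the second set. The count of 2 was 5 without ga20ox1 replicate 1, 0 without ga20ox1 replicate 2 or Col-0 replicate 3, and 1 without Col-0 replicate 1 or ga20ox1 replicate 3. It was 93 with array quality weights, with 41 higher and 52 lower, and 0 when only the groups compared entered the fit. AT1G47400 kept its call only without ga20ox1 replicate 1 (otherwise adjusted p up to 0.34; range over all alternatives 0.0012 to 0.34).

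GA20OX1-OE was compared with Col-0 for the effect of the GA20OX1 transgene alone. Limma called 0 probe sets higher and 3 lower, named after their values were seen: AT1G47400 (-1.65, SE 0.28), AT1G30260 (-0.95, SE 0.16) and the unnamed 248103_at (-0.68, SE 0.11), each with adjusted p = 0.041. For AT1G47400 Col-0 had the highest mean of all genotypes, as given above. An unadjusted p under 0.05 was found for 2010 probe sets. Of 10 autophagy genes of the ATG8 group and relatives, 4 were lower when adjusted over the list alone, ATG8D (-0.55, SE 0.14), ATG8C (-0.49, SE 0.15), APG8H (-0.46, SE 0.14) and APG8A (-0.42, SE 0.13), and 0 over all probe sets (median -0.34, or -0.21 without GA20OX1-OE replicate 3, camera adjusted p = 5.8e-05; adjusted p = 0.33 with an estimated correlation). None of the 4 was called over the list without Col-0 replicate 1, nor any but ATG8D without GA20OX1-OE replicate 2, nor APG8H without GA20OX1-OE replicate 3. The 18 nuclear photosynthesis and chlorophyll genes had a median of -0.22 (camera adjusted p = 0.00021; adjusted p = 0.57 with an estimated correlation) and the 17 chloroplast ribosome and polymerase genes one of 0.53 (camera adjusted p = 0.00084; adjusted p = 0.58 with an estimated correlation). The count of 3 was 0 without Col-0 replicate 1, Col-0 replicate 3, GA20OX1-OE replicate 1 or GA20OX1-OE replicate 3, and 7, of them 5 higher and 2 lower, without GA20OX1-OE replicate 2. It was 4, with 2 higher and 2 lower, without Col-0 replicate 2, and 8, with 5 higher and 3 lower, with both doubted arrays left out, so that the direction of the calls was not kept. AT1G47400 kept its call only without GA20OX1-OE replicate 2 and AT1G30260 only without Col-0 replicate 2 (otherwise adjusted p up to 0.31 and 0.28).

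Because the single-genotype comparisons share the Col-0 arrays, their agreement was set against simulations with no true change. Across probe sets, which are not independent replicates, the correlation of log2 differences was 0.25 between aba2 and ABA2-OE, 0.43 between ga20ox1 and GA20OX1-OE, 0.38 between aba2 and ga20ox1, 0.37 between aba2 and GA20OX1-OE and -0.02 between ABA2-OE and GA20OX1-OE. With shared controls alone the simulated correlation was 0.48 (0.14 to 0.76) and the covariance 0.0393 (0.00584 to 0.0848). The observed covariances were 0.0445, 0.0408, 0.0490, 0.0570 and -0.00226 in the same order, so that only the last lay outside the simulated range. Without the low-signal filter that pair had a correlation of 0.40 (simulated 0.23 to 0.68) and a covariance of 0.163 (0.0527 to 0.269), inside the range. The 3 Col-0 arrays could not be parted into sets of at least 2 each, and part of any agreement may come from them. Between aba2 and ABA2-OE 4 probe sets were higher in both and 1 moved in opposite directions.

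For loss of both genes together, aba2/ga20ox1 was compared with Col-0. AT1G66850 rose by 5.34 (SE 0.98, adjusted p = 0.0012), AT3G52130 by 4.96 (SE 0.75), the defensin-like gene LCR66 by 4.33 (SE 0.93), AT5G07230 by 4.32 (SE 0.94) and AT5G55420 by 4.11 (SE 0.70). EXLA1 (-3.28, SE 0.63), COR15A (-3.2, SE 0.33, adjusted p = 2.3e-06), AT5G03120 (-2.99, SE 0.36), AT2G20670 (-2.70, SE 0.49) and AT3G46370 (-2.61, SE 0.59) fell. With the pseudocount the 5 rises stood at 3.36, 3.38, 3.01, 2.96 and 2.81, and AT3G46370 at -1.65. Of the 4 ABA-induced genes 3 fell, and 4 when adjusted over the list alone (median -1.11, camera adjusted p = 7.4e-06; adjusted p = 0.14 with an estimated correlation). Of 26 UDP-glycosyltransferase genes 7 rose and 0 fell, such as UGT71C3 (2.0, SE 0.42) and UGT72E1 (1.43, SE 0.25), with a median of 0.19, or 0.10 without aba2/ga20ox1 replicate 1 (camera adjusted p = 0.017; adjusted p = 0.29 with an estimated correlation). SWEET10 (2.87, SE 0.41) and SWEET3 (1.91, SE 0.35) led 5 rises among 12 SWEET genes, of which 3 fell. Of the 6 fixed-list expansins 2 rose and 2 fell, also over the list alone, among them EXPA15 (1.35, SE 0.23) and EXPA16 (-1.24, SE 0.21). The defensin genes PDF1.2b (3.08, SE 0.45) and PDF1.2 (2.43, SE 0.37) rose, as did CYP71B22 (1.80, SE 0.24), LHCB4.3 (1.38, SE 0.21) and the auxin conjugating gene GH3.3 (1.74, SE 0.35). HIS1-3 (-2.49, SE 0.49), TBL15 (-2.23, SE 0.40) and the leaf margin regulator gene NGA2 (-0.79, SE 0.19) fell, and so did the flower marker ACT11 (-1.24, SE 0.19). With the pseudocount SWEET10, SWEET3, UGT71C3, HIS1-3 and TBL15 stood at 2.21, 1.42, 1.23, -1.81 and -1.34.

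Limma called 580 probe sets higher and 594 lower in aba2/ga20ox1, 526 of them by 2-fold or more. Without Col-0 replicate 2 more were higher (552) than lower (508). The count of 1174 was 657 without aba2/ga20ox1 replicate 3, without which AT3G46370 also lost its call (adjusted p = 0.059; range over all alternatives 0.0023 to 0.059).

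In aba2/GA20OX1-OE against Col-0 the median of all tested probe sets was 0.107, and it was -0.007 after quantile normalization, so list medians are given on both scales. AT1G66850 rose by 7.82 (SE 0.98, adjusted p = 2.1e-05), from 3.12 ± 2.66 to 10.94 ± 0.51. ATA27 rose by 6.82 (SE 1.03), AT1G68875 by 6.29 (SE 1.30), AT5G07230 by 5.13 (SE 0.94) and AT3G52130 by 5.09 (SE 0.75). AT3G46370 (-4.72, SE 0.59), ZW9 (-3.65, SE 0.16, adjusted p = 2.6e-12), AT2G20670 (-3.27, SE 0.49), COR15A (-2.63, SE 0.33) and AT1G59930 (-2.51, SE 0.51) fell. With the pseudocount the 5 rises stood at 5.77, 5.05, 4.79, 3.72 and 3.5, and AT3G46370 and AT1G59930 at -2.42 and -1.57. SWEET10 (4.01, SE 0.41) and SWEET3 (2.87, SE 0.35) rose among 4 rises and 2 falls in the 12 SWEET genes. EXPA15 rose (1.36, SE 0.23), while EXPA16 (-1.49, SE 0.21), EXLB1 (-1.68, SE 0.25) and EXGT-A3 (-1.22, SE 0.20) fell. XTH19 (2.12, SE 0.45), TBL39 (0.90, SE 0.17), the glucosinolate transporter gene GTR2 (0.95, SE 0.17) and LHCB4.3 (0.95, SE 0.21) rose, and GSTU18 (-0.97, SE 0.18) and UBC28 (-0.77, SE 0.12) fell. With the pseudocount SWEET10, SWEET3 and XTH19 stood at 3.28, 2.29 and 1.56.

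Of the 4 ABA-induced genes 3 fell in aba2/GA20OX1-OE, also over the list alone, among them COR15B (-0.99, SE 0.20), with a median of -0.93, or -0.80 after quantile normalization (camera adjusted p = 2.8e-05; adjusted p = 0.14 with an estimated correlation). Of 18 nuclear photosynthesis and chlorophyll genes 6 fell and 1 rose (median -0.34, camera adjusted p = 5e-07; adjusted p = 0.46 with an estimated correlation). After quantile normalization their median was -0.11 and 1 fell, and 1 fell with both doubted arrays left out. Of 26 UDP-glycosyltransferase genes 4 rose and 2 fell, against 1 and 2 after quantile normalization and 0 and 0 with both arrays left out. Other-tissue markers moved beside these groups. ATA27 rose, PYK10 of the root list fell by 1.10 (SE 0.25; -0.67 without aba2/GA20OX1-OE replicate 3), and the flower list had a median of 0.52, or 0.28 after quantile normalization, with a camera adjusted p of 0.086. GA perception and DELLA genes had a median of 0.20 that turned to -0.01 after quantile normalization, and 0 of 4 were called, also over the list alone.

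Limma called 811 probe sets higher and 562 lower in aba2/GA20OX1-OE, 59.1% of them higher. After quantile normalization 619 were higher and 659 lower, and under the stricter filter, which leaves out more probe sets of low signal, 555 were higher and 540 lower. The count of 1373 was 822 without Col-0 replicate 1, 839 without aba2/GA20OX1-OE replicate 3, 801 with both doubted arrays left out, and 547 when only the arrays of both groups entered the fit. PYK10 lost its call without aba2/GA20OX1-OE replicate 3 (-0.67, adjusted p = 0.053), and its adjusted p ran from 0.00021 to 0.1 over all alternatives.

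**Figure D3:**
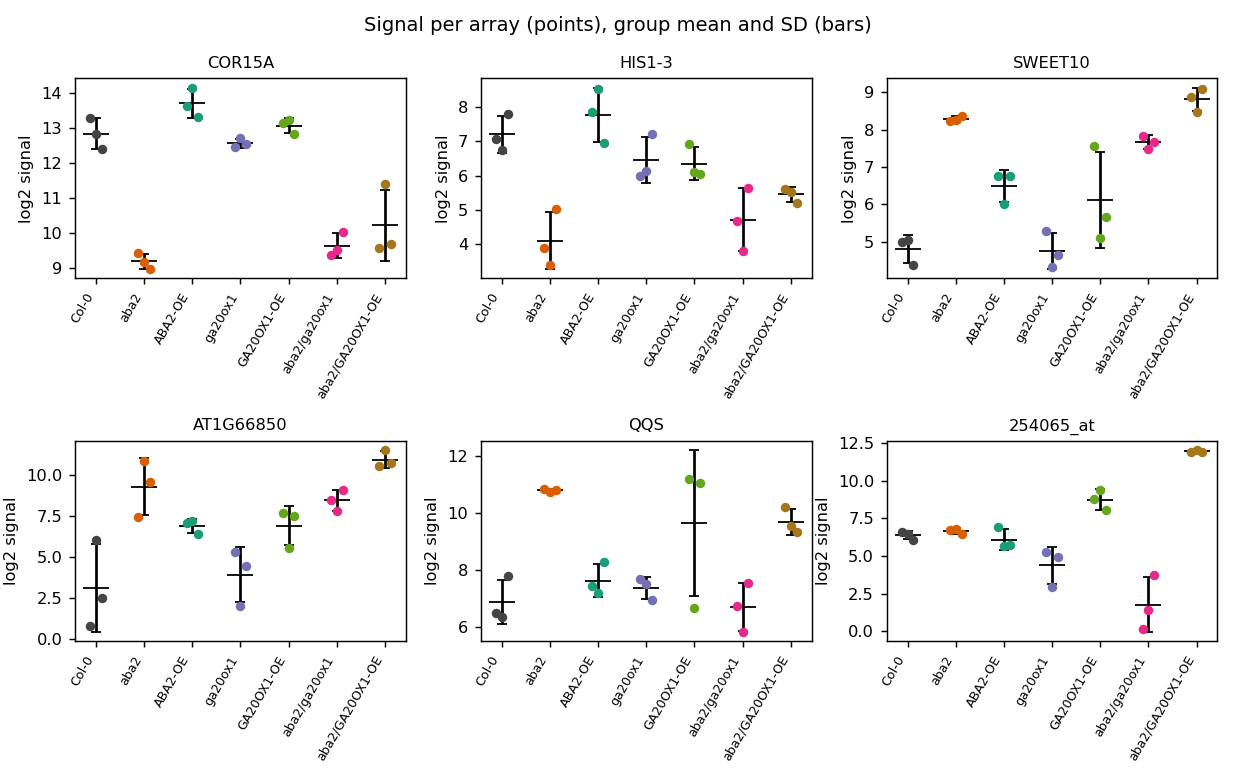
Log2 signal (y axis) of COR15A, HIS1-3, SWEET10, AT1G66850, QQS and the unnamed probe set 254065_at on each array (points) of 7 genotypes (x axis), with bars for the group mean and SD, n = 3. COR15A has a mean of 12.83 in Col-0 and 9.18 in aba2, AT1G66850 of 3.12 and 9.31, and 254065_at is highest in aba2/GA20OX1-OE.

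The effect of aba2 was then measured inside each GA background. In aba2/ga20ox1 against ga20ox1, AT5G62080, a lipid-transfer family gene, rose by 7.06 (SE 0.76, adjusted p = 4.7e-06), AT3G52130 by 5.94 (SE 0.75), AT5G07230 by 5.73 (SE 0.94), AT1G68875 by 5.26 (SE 1.30) and LCR66 by 4.78 (SE 0.93). COR15A (-2.93, SE 0.33), ZW9 (-2.50, SE 0.16), AT3G46370 (-2.47, SE 0.59), AT2G20670 (-2.38, SE 0.49) and EXLA1 (-2.21, SE 0.63) fell. With the pseudocount the 5 rises stood at 4.47, 3.66, 3.32, 2.69 and 3.25, and AT3G46370 at -1.54. Without aba2/ga20ox1 replicate 3 AT3G46370 stood at -1.61 and was not called. Of the 4 ABA-induced genes 2 fell, COR15A and COR47 (-1.22, SE 0.19), and 4 when adjusted over the list alone (median -0.95, camera adjusted p = 1.6e-05; adjusted p = 0.14 with an estimated correlation). SWEET10 rose by 2.91 (SE 0.41), XTH19 by 2.17 (SE 0.45), EXPA15 by 1.27 (SE 0.23) and UGT71C5, which encodes an ABA glucosyltransferase, by 0.83 (SE 0.18). EXPA16 (-1.39, SE 0.21) and BGLU44 (-0.81, SE 0.13) fell. With the pseudocount SWEET10 stood at 2.23 and XTH19 at 1.58. All 12 expansins together had a median of -0.02, which turned to 0.06 after quantile normalization.

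Limma called 459 probe sets higher and 408 lower between aba2/ga20ox1 and ga20ox1, and 559 in all when only these groups entered the fit. With array quality weights 1626 were higher and 1713 lower. The count of 867 was 534 without aba2/ga20ox1 replicate 1, 465 without aba2/ga20ox1 replicate 3, 460 without ga20ox1 replicate 2 and 530 without ga20ox1 replicate 3. More were lower than higher without ga20ox1 replicate 1 (546 and 502), aba2/ga20ox1 replicate 2 (375 and 364) or aba2/ga20ox1 replicate 3 (243 and 222). AT1G68875 lost its call without aba2/ga20ox1 replicate 1, aba2/ga20ox1 replicate 3 or ga20ox1 replicate 3 (adjusted p 0.059 to 0.088; range 0.00052 to 0.088). AT3G46370 lost it without ga20ox1 replicate 2, ga20ox1 replicate 3 or aba2/ga20ox1 replicate 3 (0.055 to 0.11; range 0.001 to 0.11), and EXLA1 without any 1 array but ga20ox1 replicate 1 (0.079 to 0.16; range 0.001 to 0.16).

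In aba2/GA20OX1-OE against GA20OX1-OE, AT1G68875 rose by 6.01 (SE 1.30), AT5G07230 by 4.64 (SE 0.94), ATA27 by 4.36 (SE 1.03), AT1G02813 by 4.04 (SE 0.82) and AT1G66850 by 4.02 (SE 0.98). AT3G46370 (-4.80, SE 0.59), ZW9 (-3.74, SE 0.16, adjusted p = 1.6e-12), AT2G20670 (-3.04, SE 0.49), COR15A (-2.86, SE 0.33) and AT1G59930 (-2.41, SE 0.51) fell. With the pseudocount AT1G68875, AT5G07230 and AT1G02813 stood at 3.97, 3.3 and 2.63, and AT3G46370 and AT1G59930 at -2.49 and -1.49. Without GA20OX1-OE replicate 2 AT1G68875 stood at 3.56 and AT1G02813 at 2.62, both called. With both doubted arrays left out AT1G68875 stood at 3.39 and was not called (adjusted p = 0.081; range over all alternatives 0.00014 to 0.089), and PYK10 stood at -1.02. Of the 4 ABA-induced genes 3 fell, also over the list alone (median -0.96, camera adjusted p = 4.3e-06; adjusted p = 0.14 with an estimated correlation). Of 4 GASA family genes, which respond to GA, AT5G59845 rose (1.28, SE 0.28) and 2 rose when adjusted over the list alone (median 0.70, camera adjusted p = 0.017; adjusted p = 0.14 with an estimated correlation). SWEET10 (2.70, SE 0.41), SWEET8 (2.34, SE 0.44), EXPA15 (1.38, SE 0.23), CYP71B22 (1.46, SE 0.24), UGT72E1 (1.25, SE 0.25) and LHCB4.3 (1.39, SE 0.21) rose. UGT76C2 (-1.23, SE 0.17), EXPA16 (-1.15, SE 0.21) and EXLB1 (-1.45, SE 0.25) fell, and the root marker PYK10 fell beside them (-1.62, SE 0.25).

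Limma called 434 probe sets higher and 286 lower between aba2/GA20OX1-OE and GA20OX1-OE. The count of 720 was 412 without GA20OX1-OE replicate 2, 378 when only these groups entered the fit, and 321 with both doubted arrays left out. ATA27 and AT1G66850 each lost the call without GA20OX1-OE replicate 2 (adjusted p = 0.12 for both) or aba2/GA20OX1-OE replicate 2 (0.055 and 0.072), with ranges of 0.001 to 0.19 and 0.00049 to 0.18. AT5G59845 lost it without the same arrays (up to 0.066; range 0.002 to 0.077). AT5G07230 (0.079) and AT1G59930 (0.063) lost it with both doubted arrays left out, and AT1G68875 (0.089) and AT1G02813 (0.092) when only the groups compared entered the fit.

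The 3 comparisons that add aba2 to Col-0, ga20ox1 and GA20OX1-OE share no arrays, and 160 probe sets were higher and 125 lower in all 3, against 0.32 and 0.18 expected if the calls were independent. They do share 1 estimate of spread per probe set, so the calls are not independent and these expected counts are only a rough reference. Between aba2 against Col-0 and aba2/ga20ox1 against ga20ox1, 232 were higher and 211 lower in both. The 23 genes drawn were chosen from those called in aba2 against Col-0, so only the other 2 backgrounds tested them. Of these 23, 21 were called in the same direction in ga20ox1 and 16 in GA20OX1-OE, COR15A, ZW9, SWEET10 and EXPA15 in each. Among the 7 not called in GA20OX1-OE were EXLA2 (0.03, adjusted p = 0.99) and HIS1-3 (-0.90, 0.41).

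**Figure D4:**
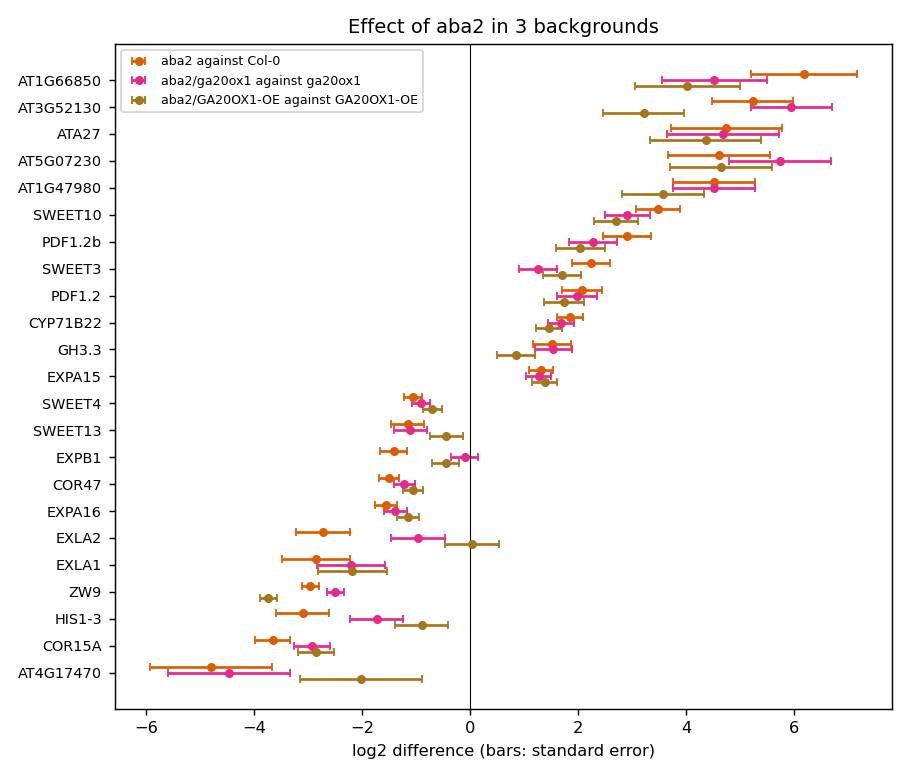
Log2 difference (x axis) of 23 genes (y axis), chosen from those called in aba2 against Col-0, when aba2 was added to Col-0, to ga20ox1 and to GA20OX1-OE, with points for the estimate and bars for its SE, n = 3 arrays per genotype. COR15A has differences of -3.66, -2.93 and -2.86 in the 3 backgrounds, and 16 of the 23 genes were called in 1 direction in the other 2 as well.

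The effect of the GA genotypes was measured inside aba2 as well. In aba2/ga20ox1 against aba2, limma called 0 probe sets higher and 1 lower, and 1033 had an unadjusted p under 0.05. The called probe set, 254065_at, is not named by the annotation and was chosen after its values were seen. It fell by 4.90 (SE 0.63, adjusted p = 0.0016), from 6.66 ± 0.21 to 1.76 ± 1.82, the latter under the low-signal bound, and the difference was -2.27 (adjusted p = 0.0033) with the pseudocount. The 26 UDP-glycosyltransferase genes had a median of 0.15, or 0.09 without aba2 replicate 2 (camera adjusted p = 0.00059; adjusted p = 0.11 with an estimated correlation) with 0 called over all probe sets. The count of 1 was 4 without aba2/ga20ox1 replicate 2 and 2 without aba2/ga20ox1 replicate 3.

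In aba2/GA20OX1-OE against aba2, AT5G40630 rose by 2.55 (SE 0.35, 5.84-fold, adjusted p = 0.00038), AT1G72230 by 2.45 (SE 0.30) and AT3G25290 by 2.3 (SE 0.30). AT3G59845 (2.68, SE 0.61) and EXLA2 (2.61, SE 0.50) rose too, the latter from 4.81 ± 1.51 to 7.41 ± 0.86. SWEET1 (-1.01, SE 0.16, adjusted p = 0.0019), AT3G46370 (-2.78, SE 0.59), AT3G44970 (-1.29, SE 0.28), AT5G55450 (-1.18, SE 0.24) and the lectin gene AT3G16530 (-1.03, SE 0.20) fell. The unnamed 254065_at, chosen after its values were seen, rose by 5.30 (SE 0.63, 39.4-fold). Among the flower markers ACT11 (1.11, SE 0.19) and INO (2.2, SE 0.48) rose, and the list had a median of 0.65, or 0.38 without aba2/GA20OX1-OE replicate 3 (camera adjusted p = 0.029; adjusted p = 0.29 with an estimated correlation). With the pseudocount EXLA2 stood at 1.88, while AT3G46370 (-1.04, adjusted p = 0.18), with both groups under the low-signal bound, and INO (1.32, 0.051) were no longer called.

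In each of 4 further lists at most 1 gene was called over all probe sets in aba2/GA20OX1-OE against aba2. Of 8 endoglucanase genes of the GH9 family GH9B8 rose (0.75, SE 0.15; list median 0.52, camera adjusted p = 0.0028; adjusted p = 0.29 with an estimated correlation), though not after quantile normalization. Of 18 TBL genes, which act in cell wall acetylation, TBL36 rose (1.11, SE 0.23; 0.73 and not called without aba2/GA20OX1-OE replicate 2; list median 0.30, camera adjusted p = 0.0087; adjusted p = 0.29 with an estimated correlation). Of 40 chloroplast-encoded photosynthesis genes 0 were called (median -0.37, camera adjusted p = 2.7e-11; adjusted p = 0.37 with an estimated correlation). The 4 ABA-induced genes had a median of 0.70, with 0 called over all probe sets and 3 higher adjusted over the list alone, COR15A by 1.03 (SE 0.33), LTI30 by 0.77 (SE 0.20) and COR47 by 0.64 (SE 0.19) (camera adjusted p = 0.0019; adjusted p = 0.34 with an estimated correlation). Without aba2/GA20OX1-OE replicate 2 COR15A stood at 0.44 and was not called over the list.

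Limma called 100 probe sets higher and 21 lower between aba2/GA20OX1-OE and aba2, and 63 in all when only these groups entered the fit. With array quality weights 387 were called. The count of 121 was 53 without aba2 replicate 1, 74 without aba2 replicate 2, 56 without aba2 replicate 3 and 43 without aba2/GA20OX1-OE replicate 2. EXLA2 lost its call without aba2/GA20OX1-OE replicate 2 (adjusted p = 0.12; range 0.0028 to 0.18) and AT3G16530 without that array, aba2 replicate 2 or aba2 replicate 3 (up to 0.13; range 0.0048 to 0.13). GH9B8 lost it without the same array, aba2 replicate 1 or aba2 replicate 3 (up to 0.12; range 0.0053 to 0.18), and TBL36 without any of these or aba2/GA20OX1-OE replicate 3 (up to 0.15; range 0.00084 to 0.19). AT3G46370 lost it without aba2 replicates 1 or 2 or aba2/GA20OX1-OE replicates 2 or 3 (up to 0.15; range 0.004 to 0.18), and AT5G55450 without any aba2 array or aba2/GA20OX1-OE replicate 2 (up to 0.15; range 0.00027 to 0.15). INO kept it only without aba2/GA20OX1-OE replicate 1 (otherwise up to 0.19), AT3G44970 only without aba2/GA20OX1-OE replicate 3 (up to 0.20), and AT3G59845 lost it without any 1 of the 6 arrays (up to 0.21). ACT11 lost it when only the groups compared entered the fit (0.077).

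Whether the GA genotypes acted differently with and without aba2 was tested as an interaction. For ga20ox1, limma called 0 probe sets, with 1156 at an unadjusted p under 0.05 and a smallest adjusted p of 0.384. The chloroplast-encoded ribosome and RNA polymerase genes had an interaction median of -0.99, with 11 of 17 lower over the list alone (camera adjusted p = 5.5e-12; adjusted p = 0.29 with an estimated correlation). For GA20OX1-OE, 6 probe sets were called, all with a more positive effect in aba2 than in the wild type, and 847 had an unadjusted p under 0.05. They were AT5G40630 (2.90, SE 0.50), AT1G72230 (2.45, SE 0.42), AT3G25290 (2.43, SE 0.42), AT3G48970 (2.07, SE 0.36) and the unnamed 247638_at (2.17, SE 0.36) and 250002_at (1.60, SE 0.27), with adjusted p = 0.028, or 0.029 for AT3G48970. The unnamed probe sets were chosen after their values were seen. So was 254065_at, which stood at 11.96 in aba2/GA20OX1-OE and 8.74 in GA20OX1-OE (3.22, adjusted p = 0.0032). Its own interaction was not called (2.93, SE 0.89, adjusted p = 0.53). GA20OX1 was not followed by name, so a transgene level that differs between these lines cannot be told apart from a dependence on aba2. The same 17 chloroplast genes had an interaction median of -0.78 here (camera adjusted p = 1.7e-09; adjusted p = 0.37 with an estimated correlation), with 0 called over all probe sets and 6 lower over the list alone. Both interactions share the Col-0 and aba2 arrays, so the second median is not an independent observation. The list had positive medians in aba2, ga20ox1 and GA20OX1-OE against Col-0, and rpoC1 was lowest in Col-0 (7.66, against 7.95 to 8.94). Low values on the Col-0 arrays alone would make both interactions negative.

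The count of 6 was 0 without any 1 of Col-0 replicates 1 and 2, the 3 aba2 arrays and GA20OX1-OE replicate 3. It was 13, all positive, without GA20OX1-OE replicate 1 and 12, of them 11 positive, without aba2/GA20OX1-OE replicate 1. The single direction was lost without GA20OX1-OE replicate 2 (2 positive and 2 negative), without aba2/GA20OX1-OE replicate 2 (1 and 1) and with both doubted arrays left out (1 and 2). Each of the 4 named genes lost its call without at least 8 of the 12 arrays in turn, with adjusted p up to 0.11 for AT5G40630, 0.13 for AT1G72230, 0.11 for AT3G25290 and 0.14 for AT3G48970.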

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

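Tests on flower tissue in the harvest, on probe sets of low signal, on a poor array and on a sample mislabelled from a genotype without the GA20OX1-OE label or with aba2 were chosen only after the results were seen. Probe sets whose response to GA20OX1-OE differed by limma's interaction test between plants with and without aba2 were AT5G40630 (2.90, SE 0.50, adjusted p = 0.028), AT1G72230 (2.45, SE 0.42, 0.028), AT3G25290 (2.43, SE 0.42, 0.028), 247638_at (2.17, SE 0.36, 0.028), AT3G48970 (2.07, SE 0.36, 0.029) and 250002_at (1.60, SE 0.27, 0.028). Inside aba2 they rose by 2.55, 2.45, 2.3, 2.41, 1.90 and 1.18 in that order. Without aba2 the differences were -0.36, 0.00, -0.13, 0.25, -0.17 and -0.41, none of them called. A transgene level that differs between the lines with and without aba2 was not tested as a cause. Of 100 splits of the same 12 arrays 8, the real one among them, gave at least the real 6 calls, and the highest other gave 1500. The split with 1500 calls set all 6 arrays carrying aba2 against the other 6, and those with 228, 122, 28 and 11 calls set 5 of them on 1 side. This points to a structure of the samples that is the aba2 genotype itself, while the splits with 33 and 16 calls set 4 and 3 of them on 1 side. In the uneven splits the aba2 difference entered the contrast, so they are no reference for an interaction alone. This test thus cannot decide on chance, which was not excluded. The single direction of the 6 calls was not kept with both doubted arrays left out, when 1 of 3 was positive.

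For the interaction of aba2 and ga20ox1 the real count was 0, so that all 100 splits gave as many, the highest of them 174. Every split that gave calls set 5 of the 6 arrays carrying aba2 on 1 side. The aba2 difference thus entered the contrast in these splits, so they are no reference for an interaction alone. For the comparisons of 3 arrays against 3 the 10 possible splits are too few for a share under 0.05. The real count and the highest of the others were 801 and 0 for aba2, 36 and 2 for ABA2-OE, 2 and 370 for ga20ox1, 3 and 1 for GA20OX1-OE, 1174 and 0 for aba2/ga20ox1 and 1373 and 0 for aba2/GA20OX1-OE, each against Col-0. They were 1 and 0 for aba2/ga20ox1 against aba2, 867 and 0 against ga20ox1, 121 and 0 for aba2/GA20OX1-OE against aba2 and 720 and 1 against GA20OX1-OE. The 370 calls came from Col-0 replicates 1 and 2 and ga20ox1 replicate 1 set against Col-0 replicate 3 and ga20ox1 replicates 2 and 3, with 297 probe sets higher in the second set and 73 lower. A split with many times the real count points to a structure of the samples other than genotype, whose source no label gives. The first set held the replicate 1 arrays of both genotypes and the second their replicate 3 arrays, while the replicate 2 arrays were divided. The split thus followed the replicate number in part, and no label says what a shared number stands for. The arrays of the first set had median signals of 135.7 to 138.5 and those of the second 144.8 to 167.9. Whether this difference in signal distribution gave the calls was not tested. That split and the real one made 2 of 10 with as many calls as ga20ox1, and in each of the other comparisons of 3 against 3 the real split was the 1 with as many.

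The first pattern weighed was the set of 5 largest named rises in aba2, AT1G66850, AT3G52130, ATA27, AT5G07230 and AT1G47980. Signals near the floor of the array were argued against, since with a pseudocount all 5 stayed called and the smallest log2 difference, that of ATA27, was 3.2 to 1 decimal, with adjusted p up to 0.0042. Flower tissue in the harvest stayed open, because ATA27 is associated with anthers and no label names the flowering stage. The other 8 tested members of the flower, pollen and meristem list had a median of 0.26, went both ways and included a fall of ACT11 by 0.86, so that this explanation cannot be told apart from an effect of aba2 in leaves. The biological explanation, loss of ABA2, is confounded with any such difference in tissue and was not tested separately. In ABA2-OE the means of the 5 genes were also above those of Col-0, at 6.90, 6.88, 5.19, 7.07 and 5.86. AT3G52130 was called there and ATA27 was not (adjusted p = 0.31). In GA20OX1-OE all 5 were higher on replicate 1 (6.92 to 7.73) than on replicate 2 (1.97 to 5.54). Higher signals of the 5 genes were thus not limited to genotypes with aba2. Among the other largest rises with aba2, LCR66 (7.88 and 2.38), AT1G68875 (6.33 and -1.16), AT5G62080 (8.53 and 4.99) and AT1G02813 (6.9 and 1.28) differed likewise between these arrays. AT5G55420 did not (5.08 and 5.37). Whether flower tissue gave the rises of these further genes was not tested and stays open too.

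The second pattern was the excess of probe sets higher in aba2/GA20OX1-OE against Col-0, 59.1% of calls. That aba2/GA20OX1-OE replicate 3 alone produced it was argued against, since without that array the share was 59.2%. Scaling of the arrays may account for it, since after quantile normalization 48.4% of calls were higher. So may probe sets of low signal, since under the stricter filter 50.7% were higher and without a filter 63.3%, although with the pseudocount it was 59.8%. A true excess of rises would also be removed by quantile normalization, so a biological explanation was not tested by it.

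The third pattern was the low signal of QQS, an orphan gene tied to starch, on GA20OX1-OE replicate 2 (6.68, against up to 11.19 in its group). A sample from a genotype without the GA20OX1-OE label was argued against, since on the probe set that parted the label most among the other arrays, 254065_at, this array lay 2.51 above the highest of the 15 arrays without the label, with an SD within groups of 0.92. A genotype with aba2 was argued against too, since on ZW9, which parted the arrays with aba2 most when this array was left out, this array lay 2.56 above the highest of them, with an SD within groups of 0.20, so that each exclusion rests on 1 probe set. A sample from outside the series and a poor array stayed open, since this array lay above all 15 on 50% (17 of 34) of the probe sets that separate the other arrays of the label, exactly the bound written beforehand, while single arrays without the label reached up to 41.8%, a reference computed afterwards. Its mean correlation with its group, 0.9735, was the highest of the 3, but by less than an SD over arrays (0.005) from 0.9716 and 0.9731, so that these explanations cannot be told apart from biological variation in this line.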

How the results depend on the processing

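The setting with both doubted arrays left out was chosen only after seeing the data, and the added gene lists were chosen after reading the probe annotation and were not planned. No named gene changed sign. Named genes were chosen as called in the main test, and the largest rises and falls outside interactions also as not overlapping between groups. For the latter no sign could turn when 1 array was left out, so kept signs say little about stability. The balance of calls turned or became even in 23 pairs of a comparison with unequal main counts and a setting, 12 of them with 1 array left out, given with their comparisons. The 11 others follow, as higher and lower. For aba2 it was 292 and 359 under the stricter filter, 330 and 402 after quantile normalization and 315 and 345 with only the groups compared, against 401 and 400. With only the groups compared it was 6 and 5 for ABA2-OE and 1 and 0 for GA20OX1-OE. It was 533 and 528 for aba2/ga20ox1 without the filter, 619 and 659 for aba2/GA20OX1-OE against Col-0 after quantile normalization, and for aba2/ga20ox1 against ga20ox1 1626 and 1713 with array weights and 588 and 607 with the block. With both doubted arrays left out it was 5 and 3 for GA20OX1-OE and 1 and 2 for the interaction. Of 258 pairs of a named gene and a comparison, 133 kept call and direction without each array in turn, 125 lost the call at least once and 0 changed sign. Call and direction were kept by 229 pairs under array quality weights, 219 without the trend, 220 without the filter, 249 with the pseudocount, 232 after quantile normalization, 258 with the replicate block, 166 with only the groups compared and 162 under the stricter filter, which tests fewer probe sets. ABA2 and GA20OX1 had no named probe set, so the planned check of the targeted genes was not run. With 3 arrays per genotype the simulated recovery was 10% at a log2 change of 0.5 and 94% at 2, and recovery near background was not simulated apart. Of 68 differences of named genes and key probe sets with at least 1 group under the low-signal bound, 60 were called with the pseudocount, and of the 2 with both groups under it 0 were.

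The counts of calls that moved by over 1.5 times were these. Without the trend ABA2-OE gave 9, GA20OX1-OE 0 and the interaction with GA20OX1-OE 2. With array quality weights ABA2-OE gave 15, ga20ox1 93, GA20OX1-OE 0, aba2/ga20ox1 against aba2 6 and against ga20ox1 3339, aba2/GA20OX1-OE against aba2 387 and against GA20OX1-OE 1384, and the interactions 23 with ga20ox1 and 10 with GA20OX1-OE. The weight of ga20ox1 replicate 2 was 7.1, and those of the others 0.46 to 2.61. With the replicate number as a block ABA2-OE gave 211, GA20OX1-OE 7 and aba2/ga20ox1 against aba2 3. No label says what a number stands for. Residuals of arrays sharing a number had a median correlation of 0.10 (31 of 63 over 0.1), against -0.04 (17 of 126) for other numbers, and 13 of 21 arrays correlated best with their own number, a hint from the data and not the design. With only the groups compared, which leaves fewer arrays to estimate the spread, ABA2-OE gave 11, ga20ox1 0, GA20OX1-OE 1, aba2/GA20OX1-OE against Col-0 547, against aba2 63 and against GA20OX1-OE 378, aba2/ga20ox1 against ga20ox1 559 and the interactions 1 and 1. Without the filter ga20ox1 gave 1 and GA20OX1-OE 0, and the correlation between aba2 and ABA2-OE was 0.41 and that between ABA2-OE and GA20OX1-OE 0.40, against -0.02 with it. With the stricter filter ga20ox1 gave 1 and aba2/ga20ox1 against aba2 0. The pseudocount gave 10 in the interaction with GA20OX1-OE, and quantile normalization 1 for ga20ox1. With both doubted arrays left out GA20OX1-OE gave 8, aba2/GA20OX1-OE against Col-0 801 and against GA20OX1-OE 321, and the interaction 3. Of 15 fixed and 44 added list calls by camera, 0 and 0 held with an estimated correlation, and fry called 6 and 12. Except where the construction is given, the cause was not tested.

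Leaving out 1 array at a time, counts ran from 491 to 739 for aba2, 3 to 242 for ABA2-OE, 0 to 5 for ga20ox1, 0 to 7 for GA20OX1-OE, 657 to 1060 for aba2/ga20ox1 and 822 to 1187 for aba2/GA20OX1-OE against Col-0. They ran from 1 to 4 for aba2/ga20ox1 against aba2 and 460 to 1048 against ga20ox1, from 43 to 157 for aba2/GA20OX1-OE against aba2 and 412 to 556 against GA20OX1-OE, and from 0 to 0 and 0 to 13 for the interactions with ga20ox1 and GA20OX1-OE.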

Other observations

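QQS varied between genotypes beyond the comparisons described. Its mean was 6.88 ± 0.78 (SD, n = 3) in Col-0 and 10.79 ± 0.04 in aba2, a rise of 15.1-fold (3.92, SE 0.74, limma adjusted p = 0.0018), and it was also higher in aba2/GA20OX1-OE (9.69; 2.81, SE 0.74, 0.019) than in Col-0. GA20OX1-OE without aba2 stood at 9.64 ± 2.57 (2.76 above Col-0, 0.22, not called), with arrays from 6.68 to 11.19. Adding aba2 was not called in GA20OX1-OE (0.05, 0.99) or in ga20ox1 (-0.67, 0.66), so the level in aba2/GA20OX1-OE cannot be tied to aba2 from these values. In aba2/ga20ox1 it stood at 6.70, a difference from aba2 of -4.09 that was not called (0.12), and the interaction of aba2 and ga20ox1 was -4.59 (SE 1.04, 0.46). The gene was chosen after its values were seen.

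The unnamed probe set 254065_at, also chosen after its values were seen, differed between genotypes. Its mean was 6.37 in Col-0, 4.38 in ga20ox1, 1.76 in aba2/ga20ox1, 8.74 in GA20OX1-OE and 11.96 in aba2/GA20OX1-OE. Against Col-0 the differences were called in aba2/ga20ox1 (-4.61, SE 0.63, adjusted p = 5.6e-05) and aba2/GA20OX1-OE (5.59, SE 0.63, 6.4e-06) but not in GA20OX1-OE (2.37, 0.22) or ga20ox1 (-1.99, 0.51). It was also called when aba2 was added to GA20OX1-OE (3.22, 0.0032) and to ga20ox1 (-2.62, 0.015), the latter with both groups under the low-signal bound. In aba2/ga20ox1 its signal was 3.39, and with the pseudocount the differences were -2.03 (0.00014) from Col-0 and -0.78 (0.15, not called) from ga20ox1. Its identity was not stated by the annotation used here.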
